A study of Mus musculus with 40 samples.

How the data were processed

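The series holds 40 Affymetrix arrays of mouse CD4 T cells from C57Bl/6 mice in 2 experiments on different array types, which were analysed apart. The sorted T cell experiment has 8 arrays. Per the labels' protocols, cells of Foxp3-GFP reporter mice were sorted, with a CD4+ CD45RBlow GFP+ gate for regulatory T cells (Treg), and cultured for 48 h in RPMI with 10% serum, either unstimulated or with antibodies to CD3 and CD28. RNA was extracted on columns and 1 µg was labelled by the Affymetrix 2-cycle protocol. The groups are activated Treg (3 arrays), resting Treg (3 arrays) and resting conventional T cells (2 arrays). The labels give bone marrow as the source of these cells, and this was not used to describe them.

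The ligand experiment has 32 arrays. Per the labels' protocols, CD4+ CD45RBlow YFP+ Treg from spleen and lymph nodes were stimulated with IL-2 (100 U/mL), dissolved antibody to CD28 (2 µg/mL) and plate-bound antibody to CD3 (1 µg/mL), with an immobilised semaphorin-4a fusion protein (Sema4a-Ig) or control IgG1 at 10 µg/mL. RNA was extracted with TRIzol and labelled by the Affymetrix 3' IVT Express protocol. The cells came from mice with a Foxp3-driven Cre recombinase and either unmodified Nrp1 (WT) or a floxed Nrp1 gene (KO), with 8 arrays for each of the 4 combinations of genotype and treatment. The titles gave the groups. For WT with Sema4a-Ig, replicate 2, the title says WT and the genotype label says knockout, and it was grouped by its title. The labels do not say that replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

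The deposited values are on a log2 scale, as log2 signal per probe set. Per the submitters' processing notes they were made with RMA and Partek 6.6, and further steps are not given in the sources used here. In the sorted T cell experiment the mean log2 value per array lay between 6.01221 and 6.01369. In the ligand experiment the deposited log2 values showed a further step. The arrays fall into 16 pairs of 1 IgG1 and 1 Sema4a-Ig array of the same genotype with neighbouring codes in their titles, and at each of the 45141 probe sets the mean of a pair was the same for all 16 pairs, within 5.5e-05. The table of 32 arrays, with the mean of each probe set removed, has 16 singular values above 1. Any difference between pairs, and so the mean difference between the genotypes, had therefore been removed before deposit. Only the 16 Sema4a-Ig minus IgG1 differences carry information.

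This decided the tests. The design fixed before the data were examined used group means over the 32 arrays. That fit takes the paired arrays as independent, with 28 residual degrees of freedom, and understates the standard errors. The ligand experiment was therefore tested on the pair differences, with 14 residual degrees of freedom, and the fit as first designed is given as an alternative. KO against WT with IgG1, KO against WT with Sema4a-Ig, and KO with Sema4a-Ig against WT with IgG1 were also planned. In these values the first 2 equal the difference between the genotypes in the Sema4a-Ig effect times -0.5 and 0.5, so none of the 3 is reported as a comparison. For the same reason the Nrp1 level cannot be used to check the genotype labels.

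Probe sets were named from the platform annotation, with symbols updated through the Entrez identifier from a RefSeq gene table of assembly GRCm38.p6. Of 45101 probe sets in the sorted T cell experiment 35890 were listed with a gene, 932 of them with several, and 9211 were unnamed. Of 45141 in the ligand experiment 29449 were listed, 551 with several genes, and 15692 were unnamed. Probe sets of several genes and unnamed ones were left out, and each gene was represented by the 1 probe set with the highest mean over all arrays of its platform. This left 18193 and 17097 genes, 16684 of them in both. Among called genes with other probe sets, 1 (Cds2, Sema4a-Ig in WT) had a probe set called in the opposite direction. No column of per-sample values was left unused, and genome coordinates are not given because no genome build is named for the arrays.

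Genes were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of 0.05. The 8 sorted T cell arrays entered 1 fit with 3 group means (5 residual degrees of freedom), and the 16 pair differences entered 1 fit with a mean per genotype. The difference of the 2 means tests whether the Sema4a-Ig effect depends on genotype. On simulated data with 200 changed genes among 18193, 44% of changes of 1 and 82% of changes of 2 on the log2 scale were called for activated against resting Treg. Among 17097 genes, 69% of changes of 0.5 and 98% of changes of 1 were called for Sema4a-Ig in WT, and 41% and 93% for the difference between genotypes. In these 3 simulations 2.33%, 2.91% and 7.59% of the calls were false. Each was run once, with few false calls (11 of 145 in the last). Whether calls for the difference between genotypes are less secure than the threshold states therefore stays open. The numbers of arrays limit the precision.

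21 gene lists were fixed before the data were examined, and the 20 with at least 5 measured members were tested. They cover the Treg signature, naive conventional T cells, effector transcription factors and cytokines, FOXO targets and quiescence, PI3K, Akt and mTOR, apoptosis and the Bcl2 family, glycolysis, sterol and fatty acid synthesis, the cell cycle, T cell receptor (TCR) activation, the interferon response, semaphorins and plexins, stress responses, ribosomal proteins, chemokine receptors and adhesion, and markers of B cells, myeloid cells, dendritic cells with MHC class II, CD8 and NK cells, and erythroid cells. Their subjects overlap with those of the published study. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. In the ligand experiment each list also has a score per pair, the mean Sema4a-Ig minus IgG1 difference of its members. These scores, and one of the genes changed by activation in the sorted T cell experiment, were compared between genotypes with a two-sided exact permutation test over 12870 relabellings, and within a genotype with an exact sign-flip permutation test over 256 sign patterns, adjusted over 21 scores. The scores and their tests were added after the data had been seen, and so was the ratio of KO to WT effects, for which the 400 genes with the largest effects relative to their spread were chosen on 4 WT pairs and measured in the other 4 and in KO, over 70 splits. The genes that differed between the sorted T cell groups, up to 200 per direction, were tested as sets in the ligand experiment.

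The genes named follow a rule fixed beforehand. Nrp1 and Foxp3 are always given. The 10 called genes with the largest log2 fold change in each direction follow, without predicted and clone-named genes. From each list up to 4 called members with the smallest adjusted p are named, and where none passed up to 2 members are given as values. For Sema4a-Ig in KO and for the difference between genotypes, where no gene passed, the members chosen in this last way are not printed and the lists are given as counts. Where no gene passes, the 5 with the smallest p are given as values. Myeloid and Treg signature genes beyond these are named because of their level.

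RNA quality was read from the control probe sets as the log2 signal of the 3' minus the 5' probe set of Actb, and for the covariate in the ligand experiment as the mean of this value for Actb and Gapdh. The alternatives were all probe sets, leaving out genes with a mean below the median, repeated quantile normalization, eBayes with trend and robust, array weights, other thresholds, fits on the compared groups alone, blocks on title codes, and leaving out each replicate. The other grouping of the WT array with conflicting labels is the same as leaving its pair out, since the pair would hold 1 array of each genotype. Blocks on the Actb signal, covariates for the 3' minus 5' signal and for the myeloid score, and leaving out each pair were added after the data had been seen.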

Results

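The arrays measured RNA levels in mouse cells labelled as Treg, a CD4 T cell lineage defined by the transcription factor Foxp3, and as conventional CD4 T cells. In the sorted T cell experiment, 3 arrays of activated Treg, 3 of resting Treg and 2 of resting conventional T cells gave log2 signals for 18193 genes. In the ligand experiment, 8 pairs of arrays from WT Treg and 8 pairs from Treg with a floxed Nrp1 gene (KO) gave Sema4a-Ig minus IgG1 differences for 17097 genes. Nrp1 (neuropilin-1) is a cell surface receptor that the series title links to semaphorin-4a and to Treg stability. Fold changes are on the log2 scale of the deposited values and are given with their standard errors.

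Resting Treg and resting conventional T cells were compared to ask what sets Treg apart without stimulation. Resting Treg had far more RNA of the genes that define the lineage. Foxp3 (Entrez 20371) had a mean log2 signal of 10.44 ± 0.14 (SD, n = 3) in resting Treg and 4.0 ± 0.07 (SD, n = 2) in conventional T cells, a difference of 6.44 ± 0.16. Nrp1 (Entrez 18186) was higher by 5.32 ± 0.19 (12.61 against 7.29). Sema4a (Entrez 20351), the ligand gene of the series, was lower in Treg (log2 fold change -2.41 ± 0.24). In all, 1008 genes differed in limma's test, 704 higher and 304 lower in Treg.

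The largest increases were in Niban1 (6.90), Foxp3, Ikzf2 (6.22), which encodes Helios, the inhibitory receptor gene Ctla4 (6.20), Ahnak (5.86), Hdac9 (5.72), Cd83 (5.71), Plagl1 (5.71), the integrin gene Itgae (5.71) and Pdcd1 (5.65), which encodes PD-1. The largest decreases were in Lypd6b (-5.69), Pdlim4 (-5.68), Igfbp4 (-5.11), Atp8b4 (-4.97), Klrd1 (-4.73), the phosphodiesterase gene Pde3b (-4.39), Dapl1 (-4.13), App (-4.11), Arhgap29 (-4.0) and Acoxl (-3.83). Of 28 measured Treg signature genes 21 rose (24 adjusted over the list alone), and the list test passed with adjusted p = 0.0388 with an estimated correlation. Of 14 naive conventional T cell genes 5 fell, among them Lef1 (-1.55), and 1 rose (10 and 1 adjusted over the list alone). That list's call was lost, at adjusted p = 0.298 with an estimated correlation. Of 22 chemokine receptor and adhesion genes 10 rose (11 up and 2 down adjusted over the list alone), including Cxcr5 (5.18), Itgb8 (4.47) and Itgb1 (3.40), again with adjusted p = 0.298 with an estimated correlation. Of 21 FOXO and quiescence genes Foxo1 (0.82) rose and Pik3ip1 (-1.10), Rictor and Il7r (-0.77) fell (1 up and 6 down adjusted over the list alone), and the list did not pass (camera, adjusted p = 0.0700). Of 31 cell cycle genes Mki67 (2.20) rose and Ccne1 (-1.15) fell (3 up and 1 down adjusted over the list alone; camera, adjusted p = 0.580). Of 23 stress response genes Xbp1 (0.80) rose and Trib3 (-1.28) fell (1 and 1 adjusted over the list alone; camera, adjusted p = 0.563).

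Of 29 TCR activation genes 8 rose and 1 fell (8 and 1 adjusted over the list alone), with Il2ra (5.49), the high-affinity IL-2 receptor chain, Tnfrsf9 (2.91), Cd200 (2.83) and Cd44 (1.94) higher (adjusted p = 0.126 with an estimated correlation). Among 20 PI3K, Akt and mTOR genes 2 rose and 3 fell (3 and 3 adjusted over the list alone). Phlpp1, a phosphatase gene that acts against Akt, was higher by 5.01 ± 0.18 and Eif4ebp1 by 1.17, while Rictor (-1.93) and Pik3cd (-1.34) were lower, and the list as a whole did not pass (camera, adjusted p = 0.617, and 0.798 with an estimated correlation). Among 20 effector genes Maf (4.75), Rora (3.63) and Irf4 (2.26) rose and Il2 (-0.85) fell (4 up and 1 down adjusted over the list alone, adjusted p = 0.429 with an estimated correlation).

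Of 10 B cell markers 3 were higher in resting Treg (3 adjusted over the list alone): Cd79b by 2.85, Ighm by 0.77 and Cd79a by 0.73 (adjusted p = 0.429 with an estimated correlation). None of 9 dendritic cell and MHC class II markers passed over all genes, but 7 were positive and 2 passed adjusted over the list alone, H2-Aa (2.63, adjusted p over all genes = 0.114) and Cd74 (2.09, 0.105), each highest in resting Treg replicate 3. Of 16 myeloid markers 11 were positive and none passed (0 adjusted over the list alone), with values of 2.39 for Lyz1 and -0.47 for Elane. Of 6 erythroid markers none passed (0 adjusted over the list alone), with 0.15 for Alas2 and 0.07 for Car1. Of 11 CD8 and NK markers Klrd1 was lower (1 adjusted over the list alone, adjusted p = 0.429 with an estimated correlation). The Actb 3' minus 5' signal, which rises as RNA is degraded or amplified from short fragments, was 1.24 and 1.54 in conventional T cells and 5.90, 2.50 and 2.67 in resting Treg. With the 5 arrays under 4 alone, 973 genes were called, 658 of them among the 1008, and with the 2 classes of this signal as a block 1633. With 2 conventional T cell arrays, leaving 1 out gave 242 genes (without replicate 1) and 288 (without replicate 2), with the lone array assumed to vary like the others.

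Activated and resting Treg came from the same sort gate and differed in stimulation with antibodies to CD3 and CD28. Stimulated Treg had more RNA of TCR activation genes, a list that passed with an estimated correlation. Members of the cell cycle list (10 of 31) and the Treg signature (3 of 28) also rose, but these lists lost their calls, at adjusted p = 0.106 and 0.117 with an estimated correlation. Both passed with fry (adjusted p = 0.0180 each). The transcription factor genes Egr3 and Egr2 rose by 5.93 ± 0.33 and 4.95 ± 0.47, and Irf4, which TCR signals induce, by 3.73 ± 0.27. Mki67, the gene of the proliferation marker Ki-67, rose by 3.94 ± 0.40. In all, limma called 135 genes, 95 higher and 40 lower in activated Treg, and 2095 genes had an unadjusted p under 0.05. Nrp1 was lower in activated Treg by a margin that missed the threshold (-0.80 ± 0.17, adjusted p = 0.0907), and so was the difference in Foxp3 (0.37 ± 0.14, adjusted p = 0.347).

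Of 31 cell cycle genes 10 rose (24 adjusted over the list alone). Among them were Ccnb2 (4.19), which encodes cyclin B2, Top2a (3.63), the spindle checkpoint gene Bub1b (3.35), the ribonucleotide reductase gene Rrm2 (2.58) and the replication helicase gene Mcm5 (1.51). The list's call was lost, at adjusted p = 0.106 with an estimated correlation. Other proliferation-linked genes among the 10 largest increases were Cep55 (4.69), Cdca8 (4.10), Cenpk (3.85) and Shcbp1 (3.82). Of 29 TCR activation genes 7 rose (14 adjusted over the list alone), including Tnfrsf9 (2.90), the gene of the costimulatory receptor 4-1BB, and Egr1 (2.66), and this list passed with adjusted p = 0.00333 with an estimated correlation. Of 28 Treg signature genes 3 rose (13 up and 1 down adjusted over the list alone): Il10 (3.34), Lag3 (3.12) and Tnfrsf9 (adjusted p = 0.117 with an estimated correlation).

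The largest decreases were in Tdrp (-2.43), the stress-induced pseudokinase gene Trib3 (-1.92), Vipr1 (-1.80), Ifit1bl1 (-1.76), Kcna2 (-1.75), Rflnb (-1.73), Spon1 (-1.73), Pgm2l1 (-1.69), Rhob (-1.67) and Npff (-1.66). Of 21 FOXO and quiescence genes Klf2, which encodes a transcription factor of quiescent T cells, fell (-0.95 ± 0.16), with 4 down adjusted over the list alone and adjusted p = 0.118 with an estimated correlation. Of 20 effector genes Irf4 and Il10 rose (5 up and 1 down adjusted over the list alone, adjusted p = 0.312 with an estimated correlation). Of 14 naive T cell genes Klf2 fell (3 adjusted over the list alone, adjusted p = 0.602 with an estimated correlation). Of 28 interferon response genes Ifit2 fell (-1.15; 1 up and 3 down adjusted over the list alone), and the list did not pass (camera, adjusted p = 0.0822, and 0.571 with an estimated correlation).

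The 6 Treg arrays differed in RNA quality in a way that crossed the groups. The Actb 3' minus 5' signal was 5.87 and 6.17 in activated replicates 1 and 2 and 5.90 in resting replicate 1, and lay between 2.31 and 2.67 in the other 3. With these 2 classes as a block 317 genes were called, 132 of them among the 135, and with the arrays of the low class alone 24, from 1 activated and 2 resting Treg arrays with the spread shared with the conventional T cells. Within the high class the 95 higher genes had a median difference of 2.09, within the low class of 2.54, and the 40 lower genes had medians of -1.20 and -1.25. These genes were chosen on the same arrays, and each class sets 2 arrays against 1, so the likeness of the classes is partly fixed by the choice. The count depended on single arrays: it was 12 without activated replicate 1, 34 without resting replicate 2 and 67 without activated replicate 3. Array weights raised it to 946 genes (374 higher, 572 lower), which included the 135.

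**Figure D1:**
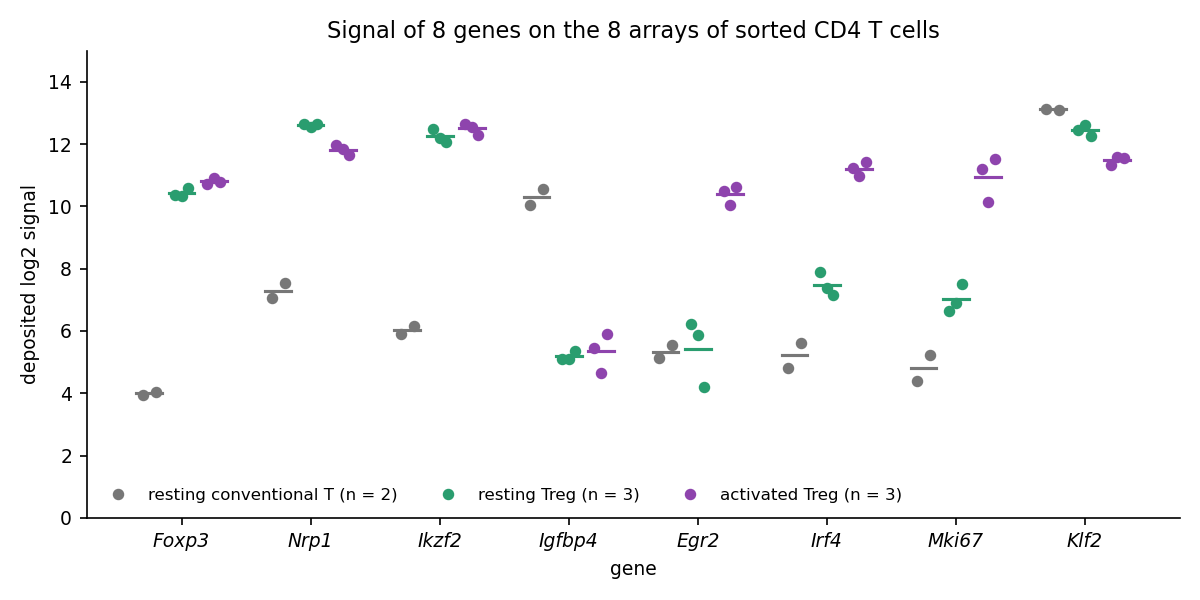
Deposited log2 signal (vertical axis) of 8 genes (horizontal axis) on each of the 8 arrays of the sorted T cell experiment, one point per array, with a short line at the mean of each group. Foxp3 and Nrp1 separate both Treg groups from conventional T cells (Foxp3 mean 4.0 in conventional T cells, 10.44 in resting and 10.81 in activated Treg), while Egr2, Irf4 and Mki67 are highest in activated Treg.

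In the ligand experiment the targeted gene was read first. The Nrp1 signal was 8.40 ± 0.13 (SD, n = 8, range 8.15 to 8.53) in WT with IgG1, 8.77 ± 0.13 (8.63 to 9.01) in WT with Sema4a-Ig, 8.41 ± 0.12 (8.18 to 8.56) in KO with IgG1 and 8.75 ± 0.12 (8.60 to 8.98) in KO with Sema4a-Ig. Because every pair had been set to the same mean before deposit (8.58 for this gene in both genotypes), these levels neither show nor rule out a loss of Nrp1 in KO. For the same reason the SDs and ranges with IgG1 and with Sema4a-Ig mirror each other within a genotype. They come from the pair differences, for every gene, and are not separate spreads between arrays. Whether the Nrp1 probe sets lie in the deleted part is not given in the sources used here. Foxp3 gave a signal of 3.61 ± 0.11 (SD, n = 8) in WT with IgG1, below the highest of 23 nonspecific control probe sets (3.95, median 2.29), so its small differences cannot be read as expression. The mean was between 3.48 and 3.61 in all 4 groups, so Foxp3 gives no evidence here that the cells are Treg, and that identity rests on the labels. In the sorted Treg, on another array type, Foxp3 was at 10.44 and 10.81. Other genes of the Treg signature had high mean signals in the ligand experiment, such as Ikzf2 (11.1), Ctla4 (11.1) and Il2ra (10.3).

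WT Treg stimulated in the presence of Sema4a-Ig or of IgG1 were compared to ask what the ligand changes. Treg given Sema4a-Ig had more RNA of the FOXO and quiescence list and of the interferon response list, which both passed with an estimated correlation. Of 29 TCR activation genes 10 had less RNA, but that list lost its call, at adjusted p = 0.175 with an estimated correlation. Klf2 rose by 1.05 ± 0.13 and its trafficking target S1pr1 by 0.71 ± 0.10, each higher in 8 of 8 pairs. The chemokine gene Xcl1 fell (-0.93 ± 0.17) and so did the transcription factor gene Irf8 (-0.92 ± 0.16), each lower in 8 of 8 pairs. In all, limma called 990 of 17097 genes, 498 higher and 492 lower, a balance that depended on single pairs (198 higher and 60 lower without WT replicate 3). The changes were small: 5 genes reached a log2 fold change of 1, and 266 reached 0.5.

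The largest increases were in the interferon-induced genes Ifit1bl1 (1.13), Ifi213 (1.01) and Gbp8 (0.99), Klf2, Itih5 (0.88), Trat1 (0.88), Pf4 (0.86), Ppm1l (0.84), Ecm1 (0.83) and Astx6 (0.82). The largest decreases were in the cytokine genes Il3 (-1.02), Pdgfb (-1.02) and Ifng (-0.85), the enzyme gene Cth (-0.98), Xcl1, Irf8, the chemokine receptor gene Ccr8 (-0.91), Ptger3 (-0.87), the chemokine gene Ccl3 (-0.86) and Rgs16 (-0.85). Nrp1 itself rose by 0.37 ± 0.09, in 8 of 8 pairs. The Foxp3 value was -0.13 ± 0.09 (adjusted p = 0.446).

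Of 26 interferon response genes 12 rose and none fell (18 and 0 adjusted over the list alone), including Oasl2 (0.80), Gbp3 (0.70), Ifit3 (0.65) and Isg20 (0.50), and the list passed with adjusted p = 0.0308 with an estimated correlation. Of 17 FOXO and quiescence genes 7 rose and none fell (10 and 0 adjusted over the list alone), with Txnip (0.77) and the cell cycle inhibitor gene Cdkn1b (0.47) beside Klf2 and S1pr1, also with adjusted p = 0.0308 with an estimated correlation. Of 29 TCR activation genes 10 fell and none rose (17 down and 1 up adjusted over the list alone), among them Ccl4 (-0.75) and Irf4 (-0.50). Of 31 cell cycle genes 4 fell (21 adjusted over the list alone): Cdc6 (-0.58), Aurkb (-0.52), Cdk1 (-0.41) and Rrm1 (-0.35). The TCR activation and cell cycle lists each lost their call, at adjusted p = 0.175 with an estimated correlation. With fry they passed (adjusted p = 0.00931 and 0.0130). Their scores were negative in 8 of 8 WT pairs (exact sign-flip permutation, each adjusted p = 0.0164 over 21 scores), in a test added after the data had been seen.

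Of 20 effector genes Ifng, Csf2 (-0.75) and Irf4 fell (1 up and 5 down adjusted over the list alone, adjusted p = 0.175 with an estimated correlation). Of 27 Treg signature genes 6 rose, including the ectonucleotidase gene Nt5e (0.53) and Nrp1, and 2 fell, Ccr8 and Lag3 (-0.54), with 8 up and 3 down adjusted over the list alone (adjusted p = 0.175 with an estimated correlation). Of 11 naive T cell genes 4 rose, with Nsg2 (0.54) beside Klf2 and S1pr1, and Bach2 (-0.29) fell (5 up and 2 down adjusted over the list alone, adjusted p = 0.175 with an estimated correlation). Among 19 glycolysis genes Slc16a1 (-0.56), the hexokinase gene Hk2 (-0.45) and Pfkl (-0.42) fell (5 adjusted over the list alone, adjusted p = 0.270 with an estimated correlation). Among 19 sterol and fatty acid synthesis genes Acaca (-0.60), the acetyl-CoA carboxylase gene, and Idi1 (-0.36) fell (6 adjusted over the list alone, adjusted p = 0.175 with an estimated correlation). Of 19 PI3K, Akt and mTOR genes Phlpp1 rose (0.27; 1 adjusted over the list alone), and the list did not pass (camera, adjusted p = 0.105).

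Markers of myeloid cells moved with the same treatment. Of 16 measured, 14 had a positive value and 3 rose (3 adjusted over the list alone): Lyz2 (0.81), Tyrobp (0.39) and Ctss (0.37), at adjusted p = 0.175 with an estimated correlation. With the myeloid score of each pair as a covariate limma called 0 genes, although 867 of the 990 kept an unadjusted p under 0.05. With the 3' minus 5' signal difference as a covariate it called 395, and all 990 kept an unadjusted p under 0.05. The count also depended on single pairs, at 258 without WT replicate 3, 413 without replicate 7 and 538 without replicate 1. Without replicate 3, 28 of the 60 named genes lost their call with no change of direction, among them Nrp1, Ifng, Csf2, Irf4, Hk2 and the 4 cell cycle genes.

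**Figure D2:**
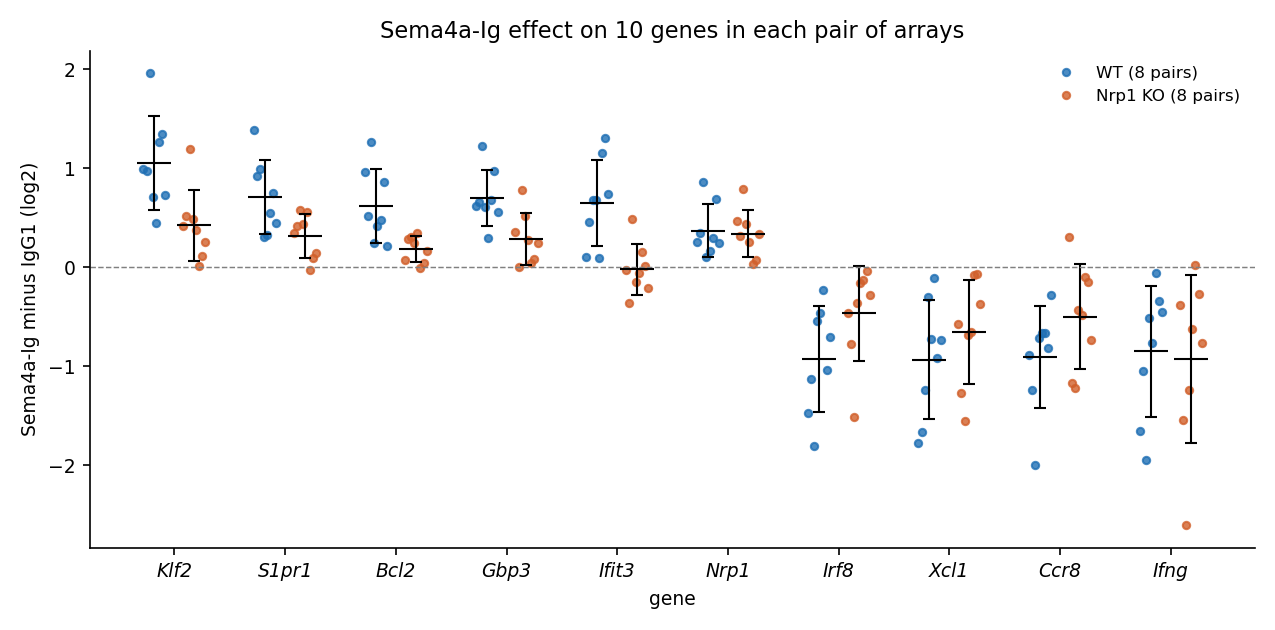
Sema4a-Ig minus IgG1 difference on the log2 scale (vertical axis) for 10 genes (horizontal axis) in each of the 8 WT and 8 KO pairs of arrays, one point per pair, with the mean and SD in black. Klf2, with a mean of 1.05 in WT and 0.42 in KO, and Irf8, with -0.92 and -0.46, have the same sign in both genotypes, as has Nrp1 (0.37, and 0.34 in KO, where no gene was called).

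The same ligand was given to Treg with a floxed Nrp1 gene to ask what its effect is in cells labelled as lacking the receptor, a loss that these values cannot show. No gene passed limma's test in KO (0 of 17097, smallest adjusted p = 0.376), while 1787 genes had an unadjusted p under 0.05, against 855 expected by chance. Much of this excess rested on replicate 3, without which 1062 genes had an unadjusted p under 0.05. The values mostly pointed the way they did in WT. The difference was 0.42 ± 0.13 for Klf2, positive in 8 of 8 pairs, and -0.66 ± 0.17 for Xcl1, negative in 8 of 8. For Nrp1 it was 0.34 ± 0.09 (adjusted p = 0.378), positive in 8 of 8. The 5 genes with the smallest p were Abhd18 (0.54), Hap1 (0.36), Trib2 (0.46), Slc45a3 (-0.46) and Gabrr2 (0.48).

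Of 29 TCR activation genes 25 had a negative value in KO and 9 passed adjusted over the list alone, and of 31 cell cycle genes 30 were negative and none passed. All 17 FOXO and quiescence genes were positive, 4 of them passing adjusted over the list alone. Of 26 interferon response genes 19 were positive and none passed. These lists passed camera's test at the preset correlation and each lost its call, at adjusted p = 0.353 for TCR activation, the cell cycle and FOXO, and 0.411 for interferon, all with an estimated correlation. Camera also passed the effector list (16 of 20 negative, 3 passing adjusted over the list alone), stress responses (16 of 22 negative, 1), naive T cell genes (8 of 11 positive, 2) and CD8 and NK markers (10 of 12 negative, 0), each losing its call at adjusted p = 0.353 with an estimated correlation. Glycolysis (17 of 19 negative, 0 passing adjusted over the list alone) and sterol and fatty acid synthesis (14 of 19 negative, 0) lost theirs at adjusted p = 0.411 with an estimated correlation, and no other list passed. Each sign-flip permutation test was exact: the KO score was 0.16 ± 0.11 (SD, n = 8 pairs) for FOXO, -0.20 ± 0.20 for TCR activation (both adjusted p = 0.0273 over 21 scores), -0.19 ± 0.24 for the cell cycle (adjusted p = 0.0469) and 0.06 ± 0.10 for interferon (adjusted p = 0.252). The effector (-0.17 ± 0.15), stress (-0.13 ± 0.12) and glycolysis (-0.11 ± 0.14) scores were negative in 8 of 8 pairs (exact permutation, each adjusted p = 0.0273). Without replicate 3 each of them lost its call at the smallest exact permutation p that 7 pairs allow (0.0156, adjusted 0.0547). No smaller p was possible, so this loss does not show that replicate 3 carried these scores. The glycolysis score was then -0.06. Replicate 3 carried much of the cell cycle value: without it the score was -0.11 ± 0.10 (n = 7 pairs, exact sign-flip permutation p = 0.0312, adjusted 0.0938), while FOXO and TCR activation kept 0.13 and -0.15 but also lost their calls (both exact permutation p = 0.0156, the smallest that 7 pairs allow, adjusted 0.0547).

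Whether the Sema4a-Ig effect depended on genotype was tested as the difference between the KO and WT effects. No single gene passed limma's test (0 of 17097, smallest adjusted p = 0.614), with 1015 genes at an unadjusted p under 0.05. The 5 with the smallest p were Tmem120b (KO minus WT 0.58), Tmem140 (-0.60), Zbtb20 (-0.64), Carns1 (-0.51) and Tctex1d4 (0.55). For Nrp1 the difference was -0.03 ± 0.13 (adjusted p = 0.993). Across 17097 genes, which are not independent replicates, the WT and KO effects had a Pearson correlation of 0.511 (jackknife SE over pairs 0.102) and a Spearman correlation of 0.458. Of all 17097 genes 64.8% had the same sign in both genotypes, and of the 990 called in WT, which were selected for their WT effect, 931.

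Of 26 interferon response genes 24 had a smaller value in KO than in WT, 9 of them passing adjusted over the list alone. The list passed camera (adjusted p = 2.35e-12) and lost its call at adjusted p = 0.130 with an estimated correlation. The FOXO list (13 of 17 smaller, 1 passing adjusted over the list alone) and the myeloid markers (13 of 16 smaller, 0 passing adjusted over the list alone) also passed camera, each at adjusted p = 0.000299, and lost their calls at adjusted p = 0.361 with an estimated correlation. The interferon score was 0.35 ± 0.22 (SD, n = 8 pairs, positive in 8) in WT and 0.06 ± 0.10 (n = 8, positive in 5) in KO, a difference of -0.29 (95% interval -0.47 to -0.11; two-sided exact permutation p = 0.00295, adjusted 0.0620 over 21 scores, past no correction). The FOXO score was 0.33 ± 0.18 in WT and 0.16 ± 0.11 in KO (n = 8 pairs each; exact permutation p = 0.0362, adjusted 0.355). For TCR activation (-0.28 ± 0.20 against -0.20 ± 0.20) and the cell cycle (-0.28 ± 0.23 against -0.19 ± 0.24) the difference was within the spread between pairs (exact permutation p = 0.457 and 0.454, n = 8 pairs each).

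**Figure D3:**
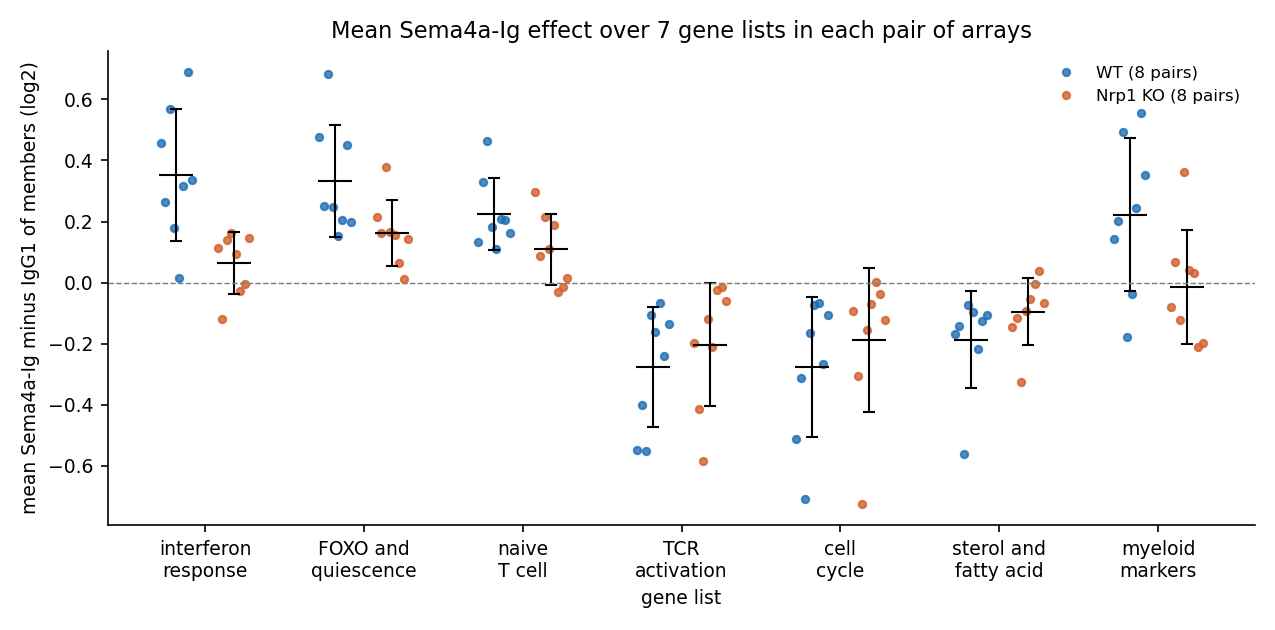
Mean Sema4a-Ig minus IgG1 difference of the members of 7 gene lists on the log2 scale (vertical axis), one point per pair of arrays, for 8 WT and 8 KO pairs, with the mean and SD in black. The interferon score lies higher in WT (mean 0.35) than in KO (0.06), and the means for TCR activation are -0.28 and -0.20, with points of the genotypes overlapping in both lists.

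**Figure D4:**
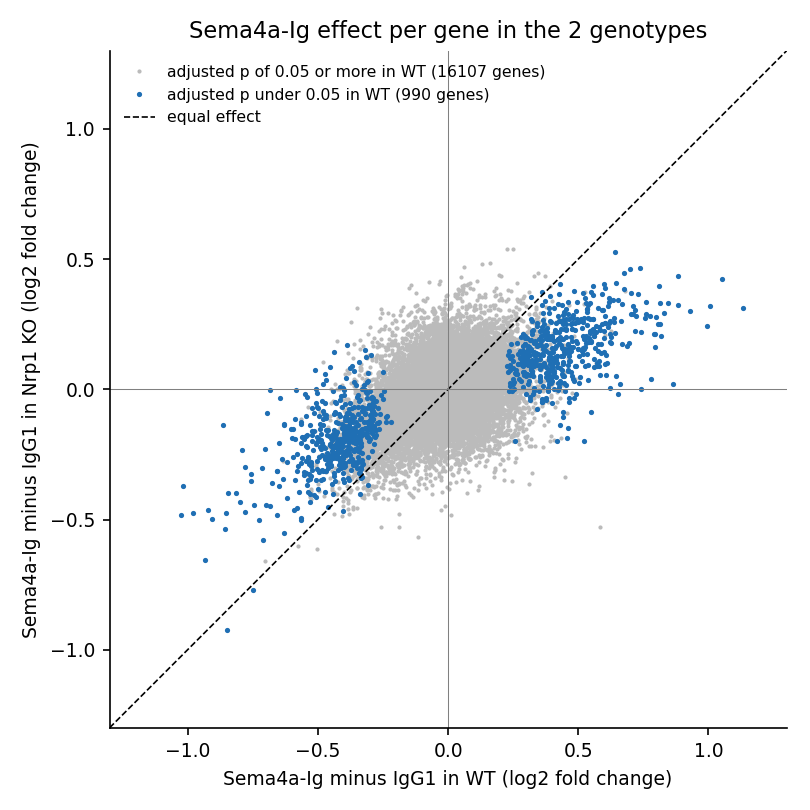
Log2 fold change of Sema4a-Ig against IgG1 in WT (horizontal axis) and in KO (vertical axis) for 17097 genes, with the 990 genes called in WT in blue, the remaining genes in grey and a dashed line for equal effects. Most blue points lie on the same side of 0 in both genotypes (931 of 990) and closer to 0 in KO, which their selection on the WT effect alone would also bring about.

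The genes that marked activation in the sorted T cell experiment were followed in the ligand experiment. Of 90 measured genes that rose on activation, 5 had a positive Sema4a-Ig value in WT and 8 were called lower (median -0.25). The set passed camera but lost its call, at adjusted p = 0.124 with an estimated correlation. Of 40 genes that fell on activation, 35 were positive in WT and 8 were called higher (median 0.17, adjusted p = 0.00728 with an estimated correlation). In KO these sets had medians of -0.17 and 0.09, with 0 genes called, and 6 of 90 and 30 of 40 positive (adjusted p = 0.194 and 0.0421 with an estimated correlation). The difference between genotypes passed for neither set with an estimated correlation (adjusted p = 0.569 and 0.195). Of 189 measured genes higher in resting Treg than in conventional T cells, 31 rose and 11 fell with Sema4a-Ig in WT (median 0.04, adjusted p = 0.124 with an estimated correlation), and of 192 lower in Treg, 17 rose and 9 fell (median -0.01, camera, adjusted p = 0.506).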

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

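Tests chosen after the results had been seen are those with the myeloid score or the 3' minus 5' signal as a covariate, the Actb classes, leaving out single pairs, the ratio of KO to held-out WT effects, and the scores per pair with the comparison of the interferon score between genotypes. What each explanation predicts was written down after the gene calls had been seen.

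Sema4a-Ig changed 990 genes in WT and 0 in KO (limma, with 1787 genes in KO at an unadjusted p under 0.05, and 1062 without KO replicate 3). Of 100 splits that exchanged Sema4a-Ig and IgG1 within WT pairs 1, the real one, gave as many genes, against 214 for the highest other. This argues against chance for the number in WT, and does not test whether WT and KO differ. Relabelling the genotypes gave as many genes at an unadjusted p under 0.05 as the real difference (1015) in 19 of 100. Chance therefore stays open for the contrast between WT and KO. Genes chosen on some WT pairs moved in KO by 0.49 of their change in the other WT pairs, with a 95% interval from 0.0906 to 0.896. For these genes this argues against lower power in KO as the whole cause (a ratio of 1). The number of pairs was the same, and the median SD of the pair differences over genes was 0.274 in WT and 0.279 in KO. Such alike spreads argue against lower power as well. The interval takes the pairs as independent, and genes chosen on KO pairs were not followed in WT. A need for Nrp1 for the whole effect (a ratio of 0) stays open because the deposited values cannot show whether, or how completely, Nrp1 was lost in KO. Single pairs carry much of the number of genes, 258 without WT replicate 3, 413 without replicate 7 and 538 without replicate 1, against 990. With the 3' minus 5' signal difference as a covariate 395 genes passed, the drop that RNA quality as the cause predicted. All 990 genes kept an unadjusted p under 0.05, and their fold changes kept a median of 0.956 of their size (quartiles 0.877 and 1.04). Their standard errors grew 1.10 times, so calls ended mainly through lost precision. RNA quality stays open as a part of the cause. With the myeloid score as a covariate the fold changes kept a median of 0.805 (quartiles 0.727 and 0.895), standard errors grew 1.25 times and 0 genes passed, so myeloid cells in the Sema4a-Ig wells, which the CD4 and YFP gate should remove, stay open too.

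The levels of the myeloid markers bear on that last point. Of the 16 markers, 9 had a mean signal above the highest nonspecific control, 0 stood in another list, and the most abundant were Ctss (10.1), Cst3 (8.69) and Lyz2 (6.47), with WT differences of 0.37, 0.17 and 0.81. Cd68 and Fcer1g, at 5.47 and 5.45, had differences of 0.05 and 0.13, and S100a8 and S100a9 of 0.45 and 0.37, none of them called.

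The interferon score differed by -0.29 between KO and WT (exact permutation p = 0.00295, adjusted 0.0620 over 21 scores, n = 8 pairs each), in the direction that a dependence on genotype would give, which remains a hypothesis. With the myeloid score as a covariate the WT score was 0.246 (95% interval 0.115 to 0.377), against 0.353 without. With the activation score it was 0.200 (0.0358 to 0.365). A rise in WT thus remained with each score, and each may account for a part. The scores measure such states only roughly and were not fitted together, so the remainder excludes neither as the whole. The difference between genotypes was not adjusted for either. The myeloid score differed the same way (0.22 in WT, -0.01 in KO, exact permutation p = 0.0525, adjusted 0.355), so myeloid cells stay open for that difference. Leaving out any 1 pair moved the difference between genotypes no further than from -0.241 to -0.338. Whether cells of both genotypes were cultured and processed together is not given in the sources used here, so a difference between such batches stays untested.

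The 6 Treg arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 135 genes, and 2 of the 10, the real one included, gave as many. The other, at 1300 genes, set activated replicates 1 and 2 and resting replicate 1 apart, the 3 arrays with a high Actb 3' minus 5' signal. These arrays also carry the lowest title codes of the experiment. RNA quality and a batch that follows the codes therefore cannot be told apart as the structure of these samples. With the Actb classes as a block 317 genes were called, so calls remained with the classes taken into account. The 135 genes kept a median of 1.02 of their fold change (quartiles 0.972 and 1.06). They had been chosen on the same arrays without the block, which disfavours genes that follow the classes. This ratio therefore cannot decide on RNA quality as a cause of their difference. Lists fixed beforehand were not chosen on these arrays. Of 31 cell cycle genes 30 were higher in activated Treg within each class (medians 1.25 in the high and 1.61 in the low class). Of 29 TCR activation genes 28 and 25 were higher (medians 0.74 and 1.19). For these lists this argues against the Actb classes as the whole cause, with only 1 array on one side of each class. Stimulation, which the design names, stays open, and no other biological explanation was tested.

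Of 184 groups of 8 pair values, list scores and named genes, 19 held a value far from the other 7 relative to their range, where chance gives about 9.2 (1 in 20). KO replicate 3 stood apart in 10 of them, and WT replicate 3, with which it shares a run of neighbouring title codes, in 5. Its scores were -0.45 for glycolysis (others -0.16 to 0.00), -0.72 for the cell cycle (others -0.31 to 0.00), -0.39 for stress responses (others -0.18 to -0.02) and -0.82 for the activation genes (others -0.39 to -0.02). Its gene values were 1.19 for Klf2 (others up to 0.51), 1.08 for Ppm1l (up to 0.47), 0.54 for Nt5e (up to 0.29), -0.72 for Hk2 (others down to -0.27), -0.62 for Pfkl (down to -0.29) and -0.73 for Rrm1 (down to -0.23). The values of WT replicate 3 were -0.56 for sterol and fatty acid synthesis (others -0.22 to -0.07), -1.39 for Fasl (down to -0.63), -1.54 for Hk2 (down to -0.50), -1.88 for Sema7a (down to -0.86) and 1.27 for Itgb7 (up to 0.59). The other 4 were -0.13 in WT replicate 2 for ribosomal proteins (others 0.00 to 0.09), -0.61 in KO replicate 2 for Bach2 (down to -0.28), -1.82 in WT replicate 1 for Acaca (down to -0.69) and -0.25 in WT replicate 5 for Cd79b (others 0.24 to 0.65).

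The FOXO and quiescence score also differed between genotypes before correction, by -0.17 (95% interval -0.33 to -0.01, exact permutation p = 0.0362, adjusted 0.355, n = 8 pairs each). No gene of 17097 had all 8 WT pairs one way and all 8 KO pairs the other.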

How the results depend on the processing

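Leaving out single pairs, the covariates, the Actb classes, the list scores, the held-out ratio and their alternatives were chosen after the data had been seen. No named gene that was called turned direction, and no list that passed did so in the list tests. Some lists that never passed had another direction with fry, such as interferon in resting Treg. The score per pair of the Treg signature in WT, 0.022 with all pairs, turned negative without WT replicate 7. The balance of calls shifted: for activation from 70.4% higher to 39.5% with array weights and 100% with the low Actb class alone, and for Sema4a-Ig in WT from 498 up and 492 down to 198 and 60 without replicate 3, 349 and 189 without replicate 1, 241 and 154 with the 3' minus 5' covariate and 696 and 958 without dim genes. For activated against resting Treg (135 genes) the count was 81 over all probe sets, 946 with array weights, 317 with the Actb classes as a block, 24 with the low class alone, 322 at an adjusted p under 0.10 with a log2 fold change of at least 0.5, 36 with the compared groups alone, and 12 to 168 leaving out 1 replicate. For resting Treg against conventional T cells (1008) it was 3005 with array weights, 1633 with the Actb block, 1576 at the looser threshold and 242 to 871 leaving out 1 replicate. For Sema4a-Ig in WT (990) it was 1558 over all probe sets, 1654 without dim genes, 395 with the 3' minus 5' covariate, 0 with the myeloid covariate, 286 at the looser p with at least 0.5, 5 with at least 1, 484 with WT pairs alone and 258 to 1069 leaving out 1 pair. The array with conflicting labels left out gave 677. Counting it as KO could not be tested, because its pair then holds 1 array of each genotype and adds nothing to the fit. In KO and for the difference between genotypes, leaving out 1 pair gave 0 each time.

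The fit with no replicate block, as first designed over 32 arrays, gave 4417 genes in WT (1749 up, 2668 down), 1734 in KO and 530 for the difference, because it counts paired arrays as independent. Runs of neighbouring title codes as a random block gave the same 4417, 1734 and 530 (correlation -0.323). Runs as a fixed replicate block gave 2468, 14 and 0, and complete runs of 4 alone 2433, 22 and 10. These fits also took single arrays with equal pair means, and so understate the standard errors as well. Their calls in KO and for the difference are therefore not read as changed genes. Beyond the pairs, the WT and KO pairs of 1 run deviated together at r = 0.23 for replicate 3 and at most 0.08 for the others. Blocks on ranges of the title codes in the sorted T cell experiment gave 73 genes for activation (47 of the 135) and 1980 for Treg against conventional T cells. Same-set correlations ran from -0.03 to 0.46, and not every array correlated best with its own set. The same-set pairs of Treg arrays gave 0.46 and 0.37, above every other pair (at most 0.26). These pairs also shared an Actb class, so pairing of the Treg arrays stays open. The causes of the other shifts were not tested, except that stricter thresholds leave fewer calls by construction.

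With an estimated correlation the number of lists past the threshold fell from 6 to 1 for activation, 9 to 1 for Treg against conventional T cells, 12 to 2 in WT, 10 to 0 in KO and 3 to 0 for the difference. Fry gave 4 for activation, 8 for Treg against conventional T cells, 12 in WT, 0 in KO and 0 for the difference. Leaving out dim genes gave 7, 6, 11, 6 and 5 in the same order. Of the sorted T cell sets, 3 passed in WT (1 with an estimated correlation, 3 with fry). In KO 2 passed (1 with an estimated correlation, 1 with fry), and for the difference 3 (0 with it, 0 with fry). The correlation of WT and KO effects rose from 0.511 to 0.677 without dim genes and was 0.418 to 0.517 leaving out 1 pair. The interferon difference was -0.241 to -0.338 leaving out 1 pair, and the ratio of KO to WT effects 0.480 with fewer and 0.515 with more genes per split. Over the alternatives, counting each gene under each alternative, called genes chosen by the naming rule stayed called in 2185 cases and lost the call in 532, and genes given as values stayed uncalled within their spread in 2472, gained a call in 149 and moved further in 10. Single lists and sets kept their outcome in 431, lost a call in 77 and gained one in 10. Some alternatives repeat the same fit. Examples are the random block of runs and the unblocked fit, the array with conflicting labels as KO and left out, and the activation sets at each set size. The cases are therefore not separate, and these totals overstate stability. Other fits of the comparisons between genotypes at 1 treatment, although listed at the start, were not run, because those contrasts hold no separate information. In the ligand experiment 117 genes had a mean signal under the median nonspecific control (2.29), where differences cannot be read. More lay under the highest one (3.95), the level by which Foxp3 was judged, and these were not counted.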

Other observations

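The splits at the end of this part were planned before they were run. The count without KO replicate 3 was chosen after the results had been seen, and no other test here was.

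Single genes of further lists changed with Sema4a-Ig in WT (limma), and none of these lists passed with an estimated correlation. Of 17 apoptosis and Bcl2 family genes Bcl2 (0.62) and Bcl2l11 (0.39) rose and Fasl (-0.51) and Bcl2l1 (-0.39) fell, with 5 up and 5 down adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.62). Of 19 chemokine receptor and adhesion genes 5 rose, among them Itgb7 (0.56) and Itga4 (0.48) beside S1pr1, and 2 fell (6 up and 3 down adjusted over the list alone, adjusted p = 0.212 with an estimated correlation). Of 22 stress response genes Atf3 (-0.78) and Sdf2l1 (-0.45) fell (4 adjusted over the list alone, adjusted p = 0.251 with an estimated correlation). Of 26 semaphorin and plexin genes Nrp1 rose and Sema7a (-0.57) fell (1 and 1 adjusted over the list alone; camera, adjusted p = 0.8). Single markers of other cells changed as well: Cd79b (0.35) of 10 B cell markers rose, and Nkg7 (-0.52) of 12 CD8 and NK markers and Klf1 (-0.30) of 6 erythroid markers fell (1 each adjusted over the list alone; camera, adjusted p = 0.319, 0.326 and 1.00). None of 7 dendritic cell and MHC class II markers and none of 23 ribosomal protein genes was called (0 adjusted over the list alone; camera, adjusted p = 0.699 and 0.319), with values of 0.16 for H2-Eb1, -0.12 for Xcr1, 0.08 for Rps14 and 0.07 for Rpl11.

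In the sorted T cells, resting Treg had more RNA than conventional T cells of the apoptosis genes Pmaip1 (3.84) and Bcl2l1 (0.81), of Slc2a1 (1.3) and Hif1a (1.35) among 18 glycolysis genes, and of Scd2 (1.84) and Fdft1 (1.62) among 21 sterol and fatty acid genes, and less of Slc16a1 (-1.70) and Pdk1 (-1.32). Of 17 apoptosis genes 2 rose (3 up and 1 down adjusted over the list alone). In the glycolysis list 3 rose and 2 fell (5 and 2 adjusted over the list alone). In the sterol and fatty acid list 2 rose (2 adjusted over the list alone). None of these lists passed (camera, adjusted p = 0.617, 0.845 and 0.356). The plexin gene Plxnc1 (2.18) was higher too, and of 26 semaphorin and plexin genes 2 rose and 1 fell (3 and 1 adjusted over the list alone, adjusted p = 0.581 with an estimated correlation). Of 28 interferon response genes 3 rose, Gbp3 (3.44), Cxcl10 (1.99) and Isg20 (1.88), and 2 fell, among them Oasl2 (-1.26) (4 and 6 adjusted over the list alone; camera, adjusted p = 0.845). Of 20 ribosomal protein genes Rps6 (-0.91) fell (1 adjusted over the list alone, adjusted p = 0.433 with an estimated correlation). On activation Scd2 rose again (1.62), while none of 18 glycolysis, 20 PI3K, 17 apoptosis, 26 semaphorin and 22 chemokine receptor genes was called by limma. Adjusted over the list alone, glycolysis had 2 up, PI3K 1 down, apoptosis 1 up, semaphorins and plexins 1 down, and chemokine receptors and adhesion 4 up and 3 down. Their values were 1.57 for Hk2 and 0.86 for Slc16a1, -0.96 for Pik3cb and -0.44 for Pik3r1, 0.89 for Bcl2l1 and -1.02 for Pmaip1, -1.07 for Sema4f, and -1.18 for Itga4 and 1.17 for Itgb8. Of 23 stress response genes Trib3 fell (2 up and 2 down adjusted over the list alone; camera, adjusted p = 0.913), and of 20 ribosomal protein genes none was called (0 adjusted over the list alone), with 0.60 for Rps6 and 0.31 for Rpl35. No marker of other cells was called on activation (1 up and 1 down of 11 CD8 and NK markers adjusted over the list alone, 0 in the B cell, myeloid, dendritic and erythroid lists), with -1.96 for Klrd1, 0.94 for Eomes, 1.27 for Lyz2, 0.32 for Mpo, -0.22 for Cd79a, -0.42 for Blk, -0.50 for Bst2, 0.21 for Itgax, -0.12 for Slc4a1 and -0.06 for Klf1.

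Exchanging Sema4a-Ig and IgG1 within KO pairs gave as many genes at an unadjusted p under 0.05 (1787) in 1 of 100 splits, the real one, with 1675 as the highest other. The count without KO replicate 3 was 1062, so this result rests largely on 1 pair. Relabelling the genotypes of the pairs gave as many as the real difference between genotypes (1015) in 19 of 100, with 1950 as the highest.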
